A study of Mus musculus with 2 samples.

How the data were processed

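Replication timing was measured in mouse 46C embryonic stem cells of the 129P2/Ola strain, grown with leukemia inhibitory factor. Cells took up 50 µM BrdU for 2 h, were fixed, stained with propidium iodide and sorted by DNA content into an early and a late S phase fraction. DNA from 10000 cells was sonicated to 100 to 600 bp, and BrdU-labelled DNA was precipitated with an antibody. It was amplified by whole-genome amplification and made into Ion Torrent libraries. There was 1 library per fraction.

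The reads were aligned with Bowtie2 to the mouse genome mm10, per the submitters' processing notes. The deposited values are a score, 1 per genomic position, that the authors computed from the early and the late library together and smoothed over 300 kb. How reads were counted, how reads with several equally good matches were treated, how both libraries were scaled to each other, and the log base and zero point of the score are not given in the sources used here. Positive values were taken as early from the early-against-late order in the name of the deposited table. This is an assumption, and a reversed order would exchange early and late throughout. The main results keep the deposited zero point, which sets what is called early, and an alternative moves it to the autosomal median. Smoothing over 300 kb joins neighbouring genes, flattens short domains and makes neighbouring positions dependent. Whole-genome amplification from few cells adds uneven coverage that cannot be measured without replicates. Copy number of the cells relative to the reference was not analysed here. The read depth is unknown, so no interval or detection limit from counts is given.

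The table held 384798 positions on chromosomes 1 to 19, X and Y, at a median spacing of 5778 bp, and 4 without a value were left out. No columns of per-sample values went unused (0). Genes came from a RefSeq gene table of GRCm38.p6, whose chromosome coordinates are those of mm10. It listed 348 genes of scaffolds and alternate sequences under chromosome names with coordinates of their own, and these were left out. Of 49595 genes on the chromosomes 48524 had a value, and of 21774 protein-coding genes 21225. A gene took the value of the position nearest to its midpoint, within 100 kb, at a median distance of 1.55 kb. The plan had been to use the transcription start site, but the gene table used here gives no strand. Both gene ends were added as alternatives after the data were seen, and for 631 protein-coding genes (2.97%) the ends differed in sign. Exons and introns were not analysed here. A planned relation with GC content needs the genome sequence, which was not used here, and it was not computed.

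The comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The 20 gene lists were 9 lists of named genes and 11 families given by a name pattern. Of the 18 blood genes 1, Hbb-b1, had no usable place in the gene table, and the 31 entries of the long gene list named 30 genes, since 1 gene was entered under 2 names. Genes named in the text were those marked beforehand, the 2 highest and 2 lowest of each list, the highest and lowest of each family, the 3 longest domains of each kind and the extreme positions of the genome. Some genes that this rule would name are not reported here, though they count in their lists. The genes given for domains, the globin, Hox, protocadherin and histone clusters, the genes beside the extreme positions, and the gene classes, antigen receptor loci and long genes outside the lists in the closing section were chosen after their values were seen.

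With 1 library per fraction, no test between conditions was possible and no p-value is given. Domains were runs of positions of one sign, ended by gaps over 300 kb and at least 300 kb long. The median of each list was placed among the medians of 10000 random lists of the same size drawn from protein-coding genes with a value. It was also placed among 10000 circular rotations of the profile along the genome, which keep clustered genes together. Both percentiles are given as a description of these libraries; the first compares with other genes, the second with other places, and since genes are mostly early the second is higher for most lists. Chromosome medians and the difference between X and the autosomes were placed among rotations in the same way, and values between percentiles 2.5 and 97.5 were taken as not standing apart. Intervals of medians over genes are 95% order-statistic intervals. They cover the spread between genes of a list, which are not replicates and are not independent where clustered, and no experimental error. Gene density was the number of protein-coding genes per 1 Mb window with at least 20 positions, set against the mean score of the window.

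Alternatives were the zero point at the autosomal median, 1 position per 300 kb, autosomes only, a split at 0.5, means for medians, other minimum runs, a band of 0.25 around 0 left out, gene-body means, genes of a list within 1 Mb counted as 1, rotations, a background of all annotated genes, and 300 kb windows or all genes for density. A group of genes counted as 1 took their mean, and the median over groups was ranked among lists of single random genes, which are unlike units. Chromosome Y was left out as an alternative added after its values were seen. The code was tested on simulated data: in a made-up profile of 988 blocks it recovered 1002 runs and gave 99.5% of positions their true sign. The made-up blocks were drawn longer than the median early and late domains found here (0.885 and 1.202 Mb). Recovery of shorter domains was therefore not tested. A list drawn mostly from positive blocks reached percentile 100, and 5% of 200 random lists fell outside the 2.5 to 97.5 range. Those random lists and their reference came from the same genes, so that share checks the code only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.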

Results

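The data were 1 early S phase library and 1 late S phase library from mouse 46C embryonic stem cells of the 129P2/Ola strain. The cells were labelled for 2 h with 50 µM bromodeoxyuridine (BrdU), a thymidine analogue that enters newly made DNA, and sorted by DNA content. The BrdU-labelled DNA of each fraction was pulled down with an antibody, amplified and sequenced on the Ion Torrent semiconductor platform. The question, as the series states it, was which parts of the chromosomes replicate early and which late. The authors set both libraries against each other in 1 smoothed score per genomic position, so every value below belongs to the pair. There were no replicate libraries, so no error between experiments can be given, and the read depth is unknown because the deposited values carry no counts. Positive scores were read as early, from the early-against-late order named by the deposited table. The log base, scaling and zero point of the score are not given in the sources used here, so it is not read as a fold.

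The genome divided into an early and a late part, with more of it late at the deposited zero point. Of 384794 positions with a value, 43.1% lay above 0 and 56.9% below. With the zero point at the autosomal median, 49.4% lay above it, a share that this choice largely fixes in advance. The true zero point is not known, so the excess of late positions is stated for the deposited one only. The distribution had a late peak at -1.35 and an early peak at 1.55, and its median was -0.33 (quartiles -1.17 and 0.88). Only 20.2% of positions lay within 0.5 of 0. The highest value of the genome, 2.20, was at position 4979969 of chromosome 7, inside Sbk3 and beside the zinc finger genes Zfp579 and Fiz1. The lowest, -2.19, was on chromosome Y at position 3885552, a chromosome where neighbours at most 7 kb apart differed by a median of 0.254, against at most 0.0149 on any other. Outside Y the lowest was -1.93, at position 107287382 of chromosome 2, beside the potassium channel gene Kcna4. Because neighbouring positions share reads through the smoothing, the share above 0 was also taken from 1 position per 300 kb. It was then 3436 of 8504, or 40.4% (95% exact binomial interval 39.4 to 41.5%). This interval covers the sampling of positions only and treats them as independent. Early and late domains had median lengths of 0.885 and 1.202 Mb, longer than 300 kb, so the interval is too narrow even for that sampling.

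**Figure D1:**
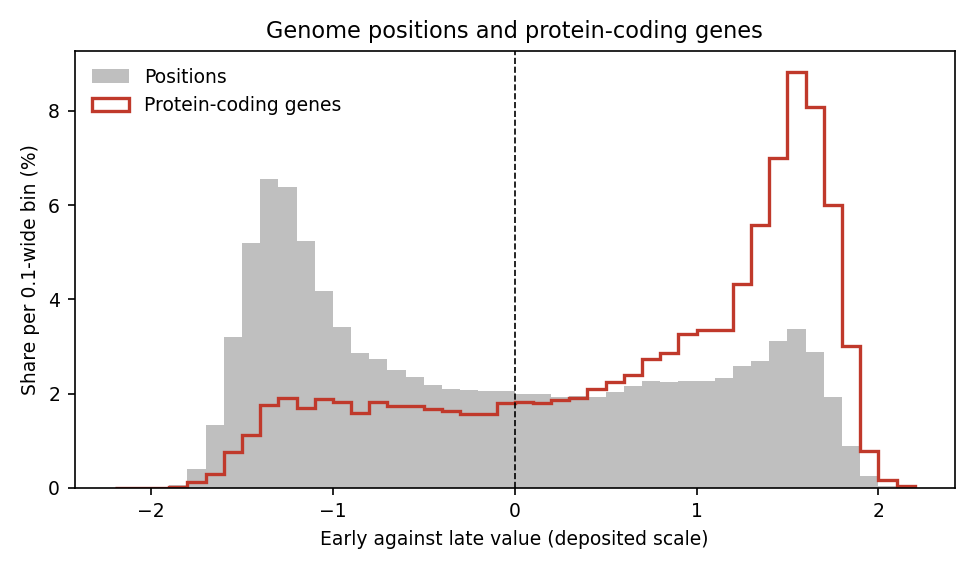
Histograms of the early against late score (x axis, deposited scale) over all positions with a value (grey) and over protein-coding genes (red outline). The y axis gives the percentage of each per 0.1-wide bin. The late peak of the positions at -1.35 and their early peak at 1.55 stand on either side of 0, and their median is -0.33.

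Early and late positions formed long runs, and the longest differed in their genes. The longest early domain ran from 75492281 to 86416737 on chromosome 15 (10.9 Mb, median 1.54) and held 258 protein-coding genes. Among them were the ribosomal protein genes Rpl8 and Rpl3, the polarity gene Scrib and the cytoskeletal linker gene Plec. The next ran from 131615499 to 142431231 on chromosome 4 (10.8 Mb, median 1.55, 206 genes) and held Lin28a, an RNA-binding protein gene of stem cells, and Rpa2, which encodes a subunit of the single-stranded DNA binding protein. The third, from 27326260 to 36300817 on chromosome 17 (8.97 Mb, median 1.51, 263 genes), held Pou5f1, which encodes the pluripotency factor Oct4. The longest late domains were far poorer in genes. The longest, from 65050136 to 78168358 on chromosome 16 (13.1 Mb, median -1.2), held 15 genes, among them the adhesion gene Cadm2 and the axon guidance receptor genes Robo1 and Robo2. The second ran from 106017462 to 118032715 on chromosome 14 (12.02 Mb, median -1.204). It held 7 genes, among them the glypican genes Gpc5 and Gpc6 and the neuronal membrane protein genes Slitrk1, Slitrk5 and Slitrk6. The third, from 106059816 to 118066110 on chromosome 1 (12.01 Mb, median -1.30), held 21 genes, among them the cell death regulator Bcl2, a serpin cluster, the cadherin genes Cdh7 and Cdh19, and Cntnap5a.

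Across the genome there were 1486 runs of one sign of at least 300 kb, 715 early and 771 late. Early domains had a median length of 0.885 Mb (quartiles 0.546 and 1.57) and late domains 1.202 Mb (quartiles 0.629 and 2.42). These lengths depend on the minimum run, with medians of 0.575 and 0.747 Mb without one and 1.207 and 1.61 Mb at 600 kb. They also depend on the zero point, which is not known: at the autosomal median the early and late medians were 0.949 and 1.07 Mb. Early domains covered 974 Mb and late domains 1451 Mb, or 1135 and 1284 Mb with that zero point, and 19 early against 53 late domains reached 5 Mb. Protein-coding genes numbered 15094 in early domains, or 15.5 per Mb, and 5153 in late domains, or 3.55 per Mb. No protein-coding gene lay in 53 of the late and 10 of the early domains. A further 615 runs were shorter than 300 kb, the width of the smoothing, and were not counted.

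Gene-rich regions mostly had early scores and gene-poor regions mostly late ones. The mean score was taken in each 1 Mb window. In windows without any protein-coding gene the median over windows was -1.24, and none of the 284 lay above 0. Windows with 1 to 4 genes had a median of -0.92, and 88 of 865 lay above 0. With 5 to 9 genes the median was -0.037, with 10 to 19 genes it was 0.82, and in the 271 windows with 20 or more genes it was 1.36. In these classes 303 of 630, 406 of 491 and 229 of 271 windows lay above 0. Across 2541 windows, Spearman's rho between gene number and score was 0.79 and Pearson's r 0.65. Both are correlations across windows of 1 pair of libraries, and windows are not independent replicates. None of 10000 rotations of the profile along the genome reached this rho, their highest being 0.49.

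Genes of basic cell functions were almost all early. All 20 housekeeping genes lay above 0, with a median of 1.54 (95% interval of the median over genes 1.40 to 1.61), from the purine salvage gene Hprt at 0.77 on chromosome X to the glycolysis gene Gapdh at 2.00 (chromosome 6, 125161852 to 125166467). Ywhaz, which encodes a 14-3-3 protein, had 1.21, beta-actin (Actb) 1.39 and the tubulin gene Tuba1b 1.72. Of 78 ribosomal protein genes 77 lay above 0, with a median of 1.47 (1.37 to 1.57). Rpl18 was the highest at 2.01, and the exception was Rpl10l at -0.97 (chromosome 12, 66283379 to 66284401), a copy of Rpl10 known for its expression in testis. Protein-coding genes as a whole had a median of 1.02, and 15597 of 21225 (73.5%) lay above 0. Against random lists of protein-coding genes of the same size, the median of the housekeeping list was above 99.6% and that of the ribosomal list above 100%. These percentiles, like those that follow, describe the lists in these libraries and are not p-values.

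Replication and pluripotency genes were also mostly early, with medians inside the range of random lists of other genes. Of 38 genes of DNA replication and S phase, 36 lay above 0, with a median of 1.19 (1.05 to 1.48). The helicase gene Mcm2 and the sliding clamp gene Pcna both had 1.15, the timing regulator Rif1 had 1.34 and the licensing factor Cdt1 had 1.56. The highest were Rpa2 at 1.84 and Rpa1 at 1.85, both subunits of the single-stranded DNA binding protein. Late scores were found for Orc4, a subunit of the origin recognition complex, at -1.07 (chromosome 2, 48902824 to 48952902) and for the cyclin gene Ccna2 at -0.24, which turned to 0.066 with the zero point at the autosomal median. Of 25 pluripotency genes 24 lay above 0, with a median of 1.25 (1.03 to 1.48). Pou5f1 had 1.58 (chromosome 17, 35506032 to 35510777), Nanog 1.64 (chromosome 6, 122707489 to 122714633) and Sox2 1.04 (chromosome 3, 34649995 to 34652461). The transcription factor genes Sall4 (1.65), Prdm14 (1.25), Esrrb (1.03), Klf4 (0.66) and Zfp42 (0.65) were early, as were the Nodal co-receptor gene Tdgf1 at 1.69, the highest of the list, Dppa2 at 0.88 and Tcl1 at 0.46. The one gene below 0 was Nr0b1, a nuclear receptor gene on chromosome X, at -0.45. The list medians were above 77.0% of random lists for replication and 79.5% for pluripotency, so neither stood outside the central 95% of random lists. Against rotations of the profile, which compare with other places in the genome and not with other genes, the percentiles were 99.99 and 100.

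Genes of other lineages, which serve in these cells as markers of cell types not yet formed, were divided. Of 24 neural progenitor genes 16 lay above 0, with a median of 0.52 (-0.07 to 1.05). The neural transcription factor genes Olig2 (0.34), Pax6 (0.64), Sox1 (1.05) and Dlx2 (1.77) and the filament gene Nes (1.72) were early. Of 21 mesoderm and endoderm genes 14 lay above 0, with a median of 0.59 (-0.11 to 1.35). The muscle factor Myf5 (-1.29), the endothelial receptor Kdr (-0.45) and the endoderm factors Gata6 (-0.40) and Sox17 (-0.28) were late, though Sox17 turned to 0.022 with the zero point at the autosomal median. Mesp1 (1.62) and Mixl1 (1.84), transcription factor genes of early mesoderm and endoderm, and the Nodal antagonist Lefty1 (1.63) were early. The medians were above 8.40% and 13.0% of random lists, within the central 95%.

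Of 17 blood genes 13 lay above 0, with a median of 1.24 (0.14 to 1.42), above 74.1% of random lists. Those of T and B cell surface proteins, Cd4 at 1.80 and Cd79a at 1.71, were the highest, and Ptprc, the gene of the CD45 antigen, was the lowest at -1.17. The globin loci lay on opposite sides. The 3 alpha-globin genes on chromosome 11 (32276600 to 32297310) had a median of 1.19, and the 5 beta-globin genes on chromosome 7 (103812524 to 103853207) had -1.17. Hbb-bs, an adult beta-globin gene, had -1.14. Of 16 liver genes 7 lay above 0, and their median of -0.42 (-0.94 to 0.90) was above only 0.22% of random lists. Tdo2 (-1.57) and Cyp3a11 (-1.38), enzymes of tryptophan breakdown and of drug metabolism, were the latest. Afp (-0.11) and Alb (0.04), neighbours on chromosome 5 that encode alpha-fetoprotein and serum albumin, lay near 0, and Afp was 0.19 with the zero point at the autosomal median. The apolipoprotein gene Apoa1 (1.56) and the glucose-6-phosphatase gene G6pc (1.88) were early. The place of the liver list outside the central 95% of random lists was lost with genes within 1 Mb counted as 1 unit (median -0.035, percentile 3.05). That setting ranked group means among single genes, which are unlike units. Against all annotated genes the liver list lay at the border (2.5). The rotation percentile was 45.0.

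Of 20 imprinted genes, which are expressed from one parental copy, 12 lay above 0, and the median was 0.33 (-0.20 to 0.81), above 4.61% of random lists. Ube3a (-0.95) and Snrpn (-0.90), neighbours on chromosome 7, were the latest, H19 had -0.18 (0.13 with the zero point at the autosomal median), and Nnat (1.51) and Zrsr1 (1.41) were the highest. With genes within 1 Mb counted as 1 unit the median was 0.54, the percentile 15.3 and 10 of 14 groups lay above 0, and against rotations the percentile was 82.9. The score does not separate the parental copies.

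Long neuronal and fragile-site genes were late without exception. The list joined very long genes of the synapse and cell adhesion with genes at common fragile sites, and all 30 lay below 0, with a median of -1.24 (-1.31 to -1.16). No random list had so low a median, and only 0.04% of rotations did. At their midpoints the catenin gene Ctnna2 (-1.48; chromosome 6, 76881637 to 77979815), Csmd1 (-1.31), Lrp1b (-1.28), the adhesion gene Cntnap2 (-1.199; chromosome 6, 45060061 to 47301393) and the reelin pathway gene Dab1 (-1.0) were all late. Auts2 (-0.72) and the mitochondrial protease gene Immp2l (-0.24) were the least late. Some of these genes crossed a timing boundary, so the late score belongs to the midpoint and not to the whole gene. At its higher-coordinate end Cntnap2 had 0.75, and Auts2 had 0.08 and 0.06 at its ends. Immp2l had 0.50 at its lower-coordinate end, and 0.061 at its midpoint with the zero point at the autosomal median.

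**Figure D2:**
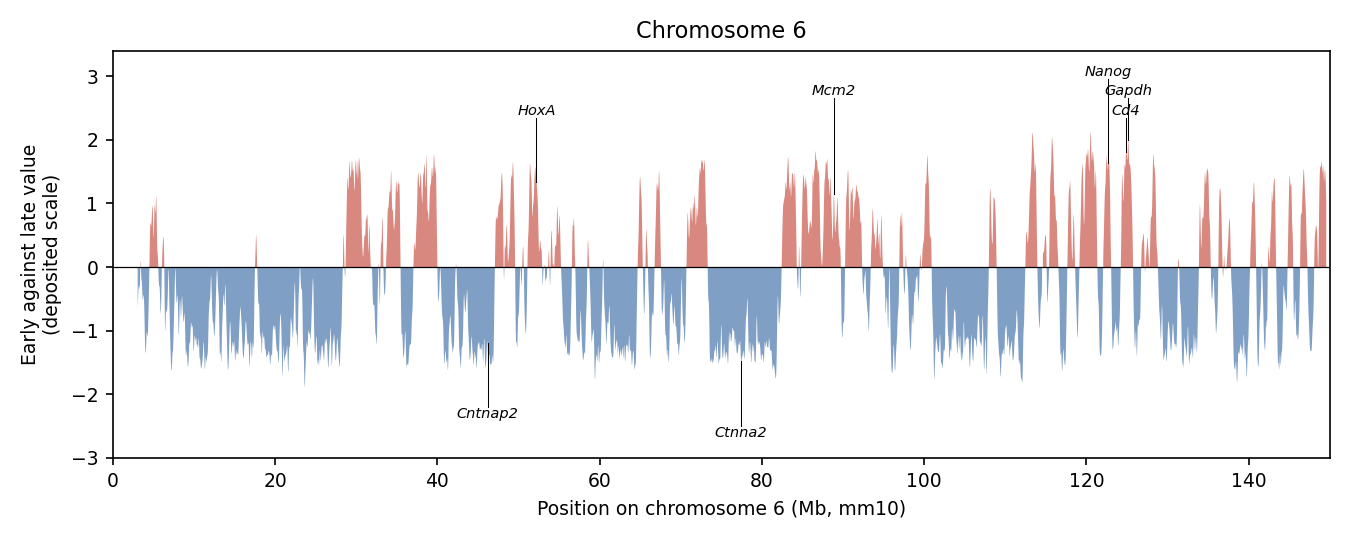
Early against late score (y axis, deposited scale) along chromosome 6 (x axis, Mb of mm10), red above 0 and blue below, with the genes of this chromosome that the text names and the HoxA cluster marked. Nanog (1.64), Cd4 (1.80) and Gapdh (2.00) stand in early regions, and the midpoints of Cntnap2 (-1.199) and Ctnna2 (-1.48) in late ones.

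All 39 Hox genes, which pattern the body axis and sit in 4 clusters, were early, with a median of 1.38 (1.33 to 1.49), above 97.3% of random lists. HoxA on chromosome 6 (52155367 to 52260880) had a median of 1.33, HoxB on chromosome 11 1.495 and HoxC on chromosome 15 1.51. HoxD on chromosome 2 (74668225 to 74765142) was lower at 0.77, with a range over its 9 genes of 0.76 to 0.78. The lowest member was Hoxd8 at 0.76 and the highest Hoxb13 at 1.58. Because each cluster is shorter than the smoothing width, its genes do not give separate measurements. Against rotations, which keep each cluster together, the percentile was 97.2.

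The sensory receptor families were mostly late. Of 1105 olfactory receptor genes 906 lay below 0, with a median of -0.82 (-0.91 to -0.73), from Olfr998 on chromosome 2 at -1.78 to Olfr279 on chromosome 15 at 1.66. Of 290 vomeronasal receptor genes, which serve pheromone detection, 240 lay below 0, with a median of -0.78 (-0.87 to -0.66), from Vmn1r228 at -1.76 to Vmn1r1 at 1.72. No random list of protein-coding genes had so low a median as either. The receptors sit in clusters, and with genes within 1 Mb counted as 1 unit the 49 olfactory groups had a median of -0.028, with 24 above and 25 below 0. The 28 vomeronasal groups had -0.48. With this grouping both medians lay below those of nearly all random lists, at percentiles 0.01 and 0. Means of groups were ranked there among single genes, which are unlike units, so these percentiles do not show that the place was kept. The rotation percentiles, 11.3 and 17.6, were inside the central 95%.

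Other families in clusters were divided within themselves. Along the clustered protocadherins on chromosome 18, cell adhesion genes of neurons, the group medians at gene midpoints were -0.72 for the alpha genes (36930285 to 37188897), -0.34 for the beta genes and 0.92 for the gamma genes (37661775 to 37841873). Each group is shorter than the smoothing width, so its genes do not give separate measurements. The rise was not steady along the locus, since Pcdhac2, at the beta side of the alpha genes (37143678 to 37187663), was the lowest at -1.22 and Pcdhgc5 the highest at 1.02. Of 104 keratin and keratin-associated genes 66 lay below 0 (median -0.30, -0.91 to -0.075), with Krtap6-2 of hair at -1.56 and the epithelial keratin Krt18 at 1.95. Among C-type lectin and Ly49 receptor genes 37 of 52 lay below 0 (median -0.76, -0.97 to -0.31), from Clec14a at -1.68 to Clec18a at 1.90, while 8 of their 13 groups lay above 0. Of 42 beta-defensin genes 22 lay above 0, with a median of 0.26 (-0.41 to 0.97), from Defb1 at -1.40 to Defb23 at 1.69. Among 19 major urinary protein genes, 14 lay below 0 (median -0.55, -0.77 to 0.16), from Mup8 at -1.198, whose nearest position was 43.5 kb away, to Mup4 at 0.74. Random lists had a median as low or lower in 0.51% of draws for the defensins, 0.02% for the urinary proteins and 0% for the other families. Against rotations all of them lay between percentiles 34.3 and 67.7. With genes within 1 Mb counted as 1 unit, the lectins formed 13 units, the keratins 6 and the defensins 5. None of these stood outside random lists (percentiles 6.75 to 41.3), and the medians turned for lectins (0.92) and defensins (-0.0076). Group means were ranked among single genes here, so these percentiles do not compare like with like. The protocadherins and the urinary proteins each formed 1 unit, the mean of all their genes (0.016 and -0.36). A single mean ranked among single genes says little, so their percentiles (26.8 and 20.5) do not decide whether they stood apart. With the zero point at the autosomal median, the medians of keratins (0.0051) and protocadherins (0.20) turned. At the lower-coordinate gene ends the protocadherin median also turned (0.11).

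Zinc finger genes with Zfp names were early in 347 of 387 cases, with a median of 1.17 (1.03 to 1.25), above 98.1% of random lists. That percentile was 95.4 on autosomes only and 81.8 with genes within 1 Mb counted as 1 unit, both inside the central 95%. Zfp579 was the highest at 2.17 and Zfp804a the lowest at -1.62. Of 67 histone genes 47 lay above 0, and the median was 0.54 (0.37 to 0.89), above 1.44% of random lists. This place below most random lists did not hold with genes within 1 Mb counted as 1 unit, where the median was 1.46 and the percentile 88.3. Nor did it hold against rotations (74.35) or all annotated genes (35.4). For the Zfp and histone genes, counting groups ranked group means among single genes, which are unlike units. The score differed between histone clusters: the 53 genes on chromosome 13 (21715711 to 23934913) had a median of 0.43 and a range of -0.81 to 1.05, and the 10 on chromosome 3 (96219885 to 96270192) had 1.46. H1f1 was the lowest at -0.81. The highest, H1f0 at 1.84, encodes a linker histone made outside S phase, which the name pattern included.

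**Figure D3:**
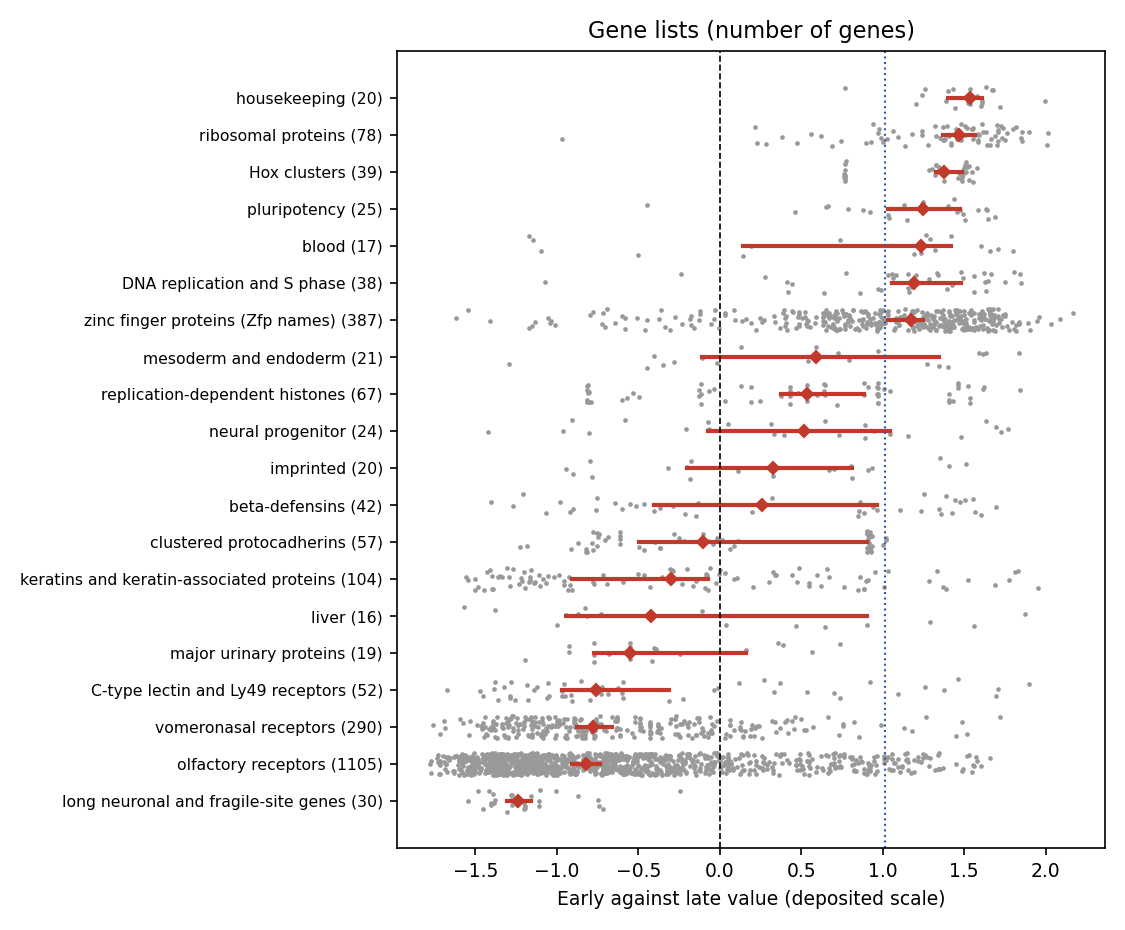
Early against late score (x axis, deposited scale) of the genes in each of the 20 lists (y axis, with the number of genes); grey points are genes, the red diamond is the median and the bar its 95% interval over genes. The dashed line is 0 and the dotted line the median of protein-coding genes, 1.02; only the 30 long neuronal and fragile-site genes lie wholly below 0.

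Chromosomes differed in their share of early positions. Chromosome 11 was the earliest, with a median of 0.71 and 60.5% of positions above 0, and 86.4% of its 1602 protein-coding genes lay above 0. Chromosome 3 was the latest by median, at -0.83, with 30.8% of positions above 0. Only these 2 chromosomes lay outside the central 95% of rotations, at percentiles 99.985 and 1.36, where 1.05 would fall outside by chance. Medians were above 0 for 6 of 21 chromosomes. Besides chromosome 11 they were chromosome 19 (0.21), 7 (0.074), 5 (0.053), 2 (0.034) and 9 (0.030), and of these chromosomes 2, 5, 7 and 9 fell below 0 with 1 position per 300 kb. With the zero point at the autosomal median 9 chromosomes lay above it, as chromosomes 4 (0.049), 13 (0.083) and 17 (0.12) turned. With means 7 lay above 0, as chromosome 17 turned to 0.017. The X chromosome had a median of -0.68 and 30.9% of positions above 0. Its median was lower than the autosomal one of -0.30 by a difference of -0.38, or -0.23 as a difference of means, and 14.4% of rotations gave a difference as low, so it did not stand apart from stretches of the same length elsewhere. Of the 901 protein-coding genes on X, 53.7% lay above 0, with a median of 0.084. Both ends of X reached less far than those of any autosome, with a 5th percentile of -1.27 against -1.55 to -1.47 and a 95th percentile of 1.26 against a lowest of 1.28 on chromosome 13.

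**Figure D4:**
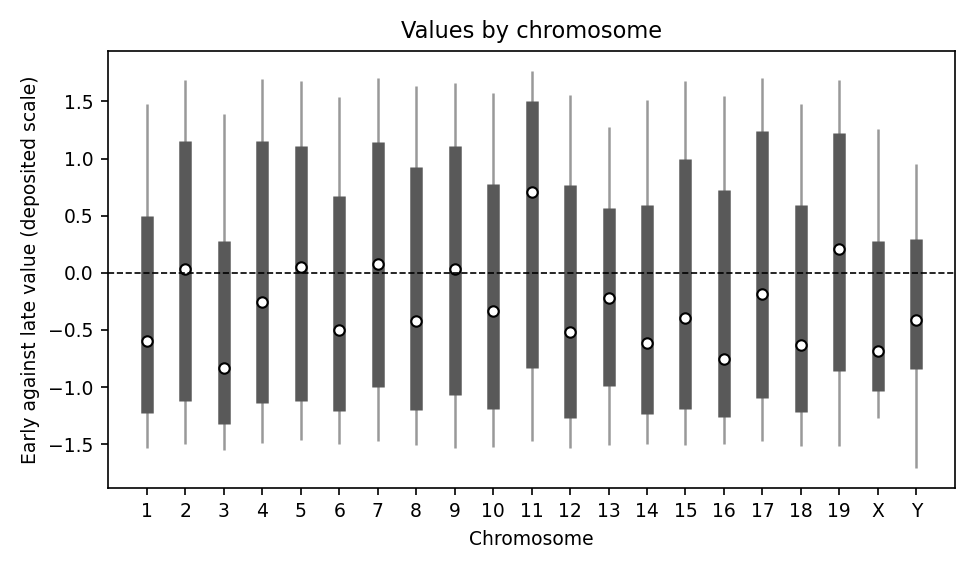
Early against late score (y axis, deposited scale) by chromosome (x axis). The dot is the median, the thick bar spans the quartiles and the thin line the 5th to 95th percentile of positions. Chromosome 11 has the highest median (0.71) and chromosome 3 the lowest (-0.83), and the late end of X (-1.27) lies closer to 0 than that of any autosome.

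**Figure D5:**
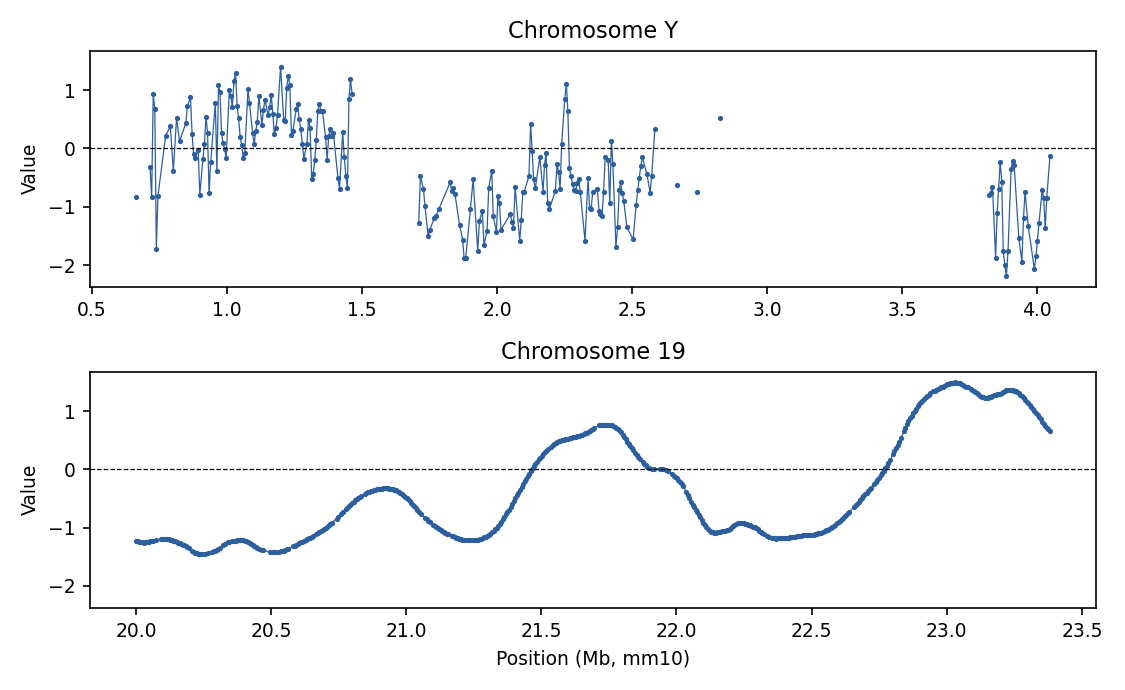
Early against late score (y axis, deposited scale) at each position with a value (points, joined where close) on chromosome Y and on a stretch of equal length on chromosome 19 (x axes, Mb of mm10). Neighbouring values jump on Y, by a median of 0.254 between neighbours at most 7 kb apart, and run smoothly on chromosome 19.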

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

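The gene-end settings and the one without chromosome Y were chosen after seeing the data; all others given here were planned. A value was counted as kept when it stayed within a factor of 1.5 for counts, within the main value's 95% interval for medians, lengths, shares and correlations, within 0.25 for single genes, and on the same side of the central range for percentiles. Of the values of the main results under alternatives, 216 were kept, 20 moved, 6 turned, 21 came to lie inside the central range and 5 outside it. Some of those kept had little or no room to change. Centring cannot alter the difference between X and the autosomes, and without chromosome Y every list median stayed the same. A gene without a position inside it kept its midpoint value under gene-body means. A percentile inside the central range under both settings counted as kept, even where rotations took it to the other side of the middle, as for neural progenitor (96.6), mesoderm and endoderm (96.0) and imprinted genes (82.9). For single genes, chromosome medians and the counts and lengths of early and late domains, 276 were kept, 118 moved and 17 turned, of which centring alone, a fixed shift of every position, gave 94 that moved and 8 that turned. The number of domains stayed between 1094 and 2101, and 12 to 14 of the 20 lists had a median above 0. Leaving out chromosome Y gave 1485 domains. The relation with GC content and its alternatives were not run. The read depth is unknown and limits every value by an amount that cannot be given. The cause was not tested for any change below, except that centring shifts every value by the same amount and that counting groups reduces the number of units.

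With the zero point at the autosomal median, 49.4% of positions lay above 0, a share that this setting largely fixes. The medians of chromosomes 4, 13 and 17 turned to 0.049, 0.083 and 0.12. List medians moved to 1.55 (pluripotency), 1.497 (replication), 1.84 (housekeeping), 1.54 (blood), -0.94 (long genes), 1.68 (Hox), -0.51 (olfactory), -0.47 (vomeronasal), 1.78 (ribosomal) and 1.48 (Zfp). Keratins (0.0051) and protocadherins (0.20) turned early, as did Ccna2 (0.066), Sox17 (0.022), Afp (0.19), Immp2l (0.061) and H19 (0.13).

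With 1 position per 300 kb, 40.4% of positions and 2 chromosome medians lay above 0, and chromosomes 2 (-0.16), 5 (-0.093), 7 (-0.096) and 9 (-0.092) turned late. Beyond 0.5 on either side, the early share was 41.8%. With means, chromosome 17 turned to 0.017 and X differed from the autosomes by -0.23. In 300 kb windows rho with gene number was 0.70.

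With genes within 1 Mb counted as 1 unit, medians moved to -0.028 (olfactory), -0.48 (vomeronasal) and 1.46 (histones), and turned for defensins (-0.0076), protocadherins (0.016) and lectins (0.92). Random-list percentiles were then 3.05 (liver), 88.3 (histones), 81.8 (Zfp), 6.75 (keratins), 11.9 (defensins), 26.8 (protocadherins), 20.5 (urinary proteins) and 41.3 (lectins), all inside the central 95%. Olfactory (0.01) and vomeronasal receptors (0), long genes (0), ribosomal (99.97) and housekeeping genes (99.6) stayed outside it. The protocadherins and the urinary proteins formed 1 unit each, the mean of all their genes, so their values under this setting say little. For the other lists with groups, means of groups were also ranked among single genes. Their percentiles under this setting do not compare like with like. On autosomes only, the Zfp percentile was 95.4. Against all annotated genes the percentiles were 98.1 (replication) and 99.9 (Hox), outside the central 95%, and 2.5 (liver, at its border), 35.4 (histones) and 13.9 (defensins), inside it.

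Against rotations, percentiles rose to 100 (pluripotency), 99.99 (replication) and 99.65 (blood), and lost their place outside the central range for liver (44.95), olfactory (11.3) and vomeronasal receptors (17.6), histones (74.35), keratins (51.8), defensins (67.7), protocadherins (55.1), urinary proteins (45.1) and lectins (34.3). At the higher-coordinate gene end the long gene median was -1.13, and Cntnap2 (0.75) and Auts2 (0.063) turned early. At the lower-coordinate end protocadherins (0.11), Auts2 (0.081) and Immp2l (0.50) did.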

Other observations

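Of the tests in this part, the one on the spacing of positions on Y was chosen only after its result was seen, and the gene classes described first were chosen after the values were seen. Most tRNA genes were early, with 358 of 403 above 0 and a median of 1.32 (95% interval over genes 1.27 to 1.37). MicroRNA genes (1227, median 1.04) resembled protein-coding genes, long non-coding RNA genes were lower (12521, median 0.52) and pseudogenes lower still (9515, median -0.18). SnoRNA genes, which guide RNA modification, had a median of -0.13 over 1317 genes, but 194 of them lay within 59 to 60 Mb of chromosome 7, beside Ube3a and Snrpn, with a median of -1.07. The other 1123 had a median of 0.37 (0.17 to 0.50).

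The antigen receptor loci, which rearrange only in lymphocytes, differed from one another. Variable segments of the T cell receptor beta locus on chromosome 6 (40891296 to 41558371) were the latest, with a median of -1.47 and 0 of 22 above 0. Those of the immunoglobulin heavy chain on chromosome 12 (120 segments, median -0.90) and kappa chain on chromosome 6 (102 segments, median -0.81) were also late. Those of the T cell receptor alpha locus on chromosome 14 (52427967 to 53876752) were near 0, with a median of 0.10 and 67 of 114 above 0. Each locus is a single stretch, so its segments are not independent values.

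Late replication of very long genes was not confined to the fixed list. Of 197 other protein-coding genes of at least 500 kb, 179 lay below 0, with a median of -1.17 (-1.23 to -1.04). The highest of the 18 above 0 were Etl4 at 1.22 on chromosome 2 and Arhgap26 at 1.04 on chromosome 18. Chromosome ends were uneven: the median of the last 5 Mb was above 0 on 11 of 20 chromosomes, and that of the first 5 Mb on 4.

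The shortest protein-coding genes, up to 4.44 kb, had a median of 0.41, below all other length classes, the lowest of which was 0.54 for the longest genes. A hypothesis was that clustered families make up the difference. Of the 4245 shortest genes 1471 belonged to families given by a name pattern, and without them the median was 1.16 (1.06 to 1.22), above the 0.54 of the longest genes. These families include the olfactory and vomeronasal receptors, mostly late in these same data, so their removal could be expected to raise the median. The rise therefore does not test the families as the source. Without family members the shortest genes still lay below the 1.37 and 1.33 of the next longer classes. They lay near the 1.15 of genes of 25.2 to 58.6 kb. No biological explanation was tested.

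The late end of X lay closer to 0 than that of any autosome. So did its early end, with a 95th percentile of 1.26 against a lowest autosomal one of 1.28 on chromosome 13, but the tests were run on the late end only. A flattening of short late domains by the smoothing is argued against by the cores of late runs of at least 2 Mb, where the X median was -1.02 (-1.05 to -0.99) and the highest autosomal one -1.18. For sparser positions on X, only positions no sparser than the autosomal median were used. There the 5th percentile on X was -0.971 (-1.11 to -0.80) and the highest autosomal one -1.27. This filter kept 3388 of 20114 positions on X, against 15794 of 27606 on chromosome 2. It also moved the 5th percentile towards 0 on every autosome and on X, there from -1.27. Since the filter itself moved the tested value and kept a smaller part of X, the test cannot tell whether sparser positions contribute. Copy number stays open as untested, and no biological explanation was tested.

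Neighbouring values on chromosome Y jumped. Wider steps between the compared neighbours alone are argued against by neighbours at most 7 kb apart. Their median difference was 0.254 (0.223 to 0.322) on Y and at most 0.0149 elsewhere. The comparison does not cover how many positions fell within the smoothing width, so sparse positions on Y stay open as an explanation. Absent smoothing on Y cannot be told apart from lighter smoothing: successive differences had a correlation of -0.0794 (-0.267 to 0.133), neither clearly negative nor near the 0.980 or more elsewhere, while neighbouring values themselves correlated at 0.809. Reads shared between repeated Y sequences were not tested, and no biological explanation was tested.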
